A study of Mus musculus with 60 samples.

How the data were processed

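RNA from the prefrontal cortex of C57BL/6J mice was sequenced after preparation with the TruSeq Stranded mRNA kit, per the labels' protocols. The labels put 60 libraries into 12 groups of 5 by genotype (HT or WT for Trip12), treatment (vehicle, fluoxetine or lithium) and sex. Replicates are numbered 1 to 5 per group.

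The deposited table holds signal values for 18088 genes in each library: gene-level read counts divided by 1 size factor per library, as DESeq2 normalized counts. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used with the genome build GRCm38. The annotation, the setting for strand, the step from transcripts to genes and the filter that left 18088 genes are not stated. Each value is a whole multiple of its library's step, so whole reads could be recovered: 100% of values were whole within a tolerance of 0.01. Size factors ran from 0.85 to 1.25. Of the gene IDs, 18077 matched the GRCm38 annotation, 11 had no symbol and 40 symbols were shared by several IDs; all 60 columns were used.

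The main test was limma-trend 3.58.1 in R 4.3.3 on log2(normalized count + 1), with 1 mean for each of the 12 groups over all 60 libraries (48 residual degrees of freedom). The design had assumed counts with edgeR first and named limma-trend for values that the authors had normalized, which is what the table holds. Genes with at least 10 normalized counts in at least 5 libraries were kept: 17804 were tested and 284 removed. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and all p-values are two-sided unless stated. The median SE of a log2 fold change between groups of 5 was 0.105. The test steps were checked on simulated counts with known changes before use.

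Contrasts compared genotypes within each treatment and sex, each drug with vehicle and with the other drug within each genotype and sex, their averages over sexes, the interactions of genotype, drug and sex, and the sexes in WT vehicle. After the data had been examined, 3 contrasts averaged over all arms were added. The text names genes by a fixed rule. In each contrast these are Trip12 and, among called genes with a mean of at least 50 normalized counts, the 10 largest rises and 10 largest falls. For each called list they are up to 4 members with the smallest p, and where fewer than 5 genes pass, also the 5 smallest p as values. Genes with only a Gm or Rik name are left out, and fewer are printed in short contrasts, from the top of each order. One gene that the rule picks is not reported here.

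Before the data were examined 39 lists of pathway, organelle and cell-type genes were fixed, with 2 more for sex. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether members move on balance one way and does not compare a list with other genes. An exact permutation of each list's mean score between the groups, within sex, was added later. List scores, depth and slopes per library were compared between groups by exact permutation tests. The length and GC slopes of a library are its coefficients from a regression of centred log2 values on log2 gene length and GC content over genes with a mean of at least 100 normalized counts; 99.94% of genes tested had a length.

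Alternatives were TMM rescaling, quantile normalization, no filter, a filter at 50, pseudocounts of 0.5 and 5, DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads, array weights, only the libraries compared, a replicate block, 2 surrogate variables from sva 3.50.0, and each library left out in turn. Covariates for depth, for length and GC slopes and for marker scores, the removal of 2 libraries together, edgeR and reads thinned to the shallowest library were added after the data had been examined. For each model 100 splits of the libraries were drawn. Correlations of responses that share vehicle libraries were set against simulated groups with no effect. Because the counting is not stated to use strand, reads of a gene and an overlapping or antisense partner may not be separable, and genes with near-identical copies (Hspa1b, ribosomal protein genes with pseudogenes, Bc1) are uncertain. No batch or date is in the labels.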

Results

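Messenger RNA was sequenced from the prefrontal cortex of C57BL/6J mice killed on postnatal day 25, in 60 libraries that fall into 12 groups of 5. The groups cross 2 genotypes of Trip12 (labelled HT, heterozygous, and WT, wild type), both sexes, and 3 treatments given through the dam's milk from postnatal day 3 to 24. These were vehicle, fluoxetine (a selective serotonin reuptake inhibitor) and lithium (a mood stabiliser that inhibits glycogen synthase kinase 3 and inositol monophosphatase). Whole reads could be recovered from the normalized counts, and their totals ran from 25.1 to 36.6 M per library (M, mega). Depth followed treatment: vehicle libraries held 26.6 to 31 M reads, fluoxetine libraries 32.7 to 36.6 M, lithium females 32.1 to 35.9 M and lithium males 25.1 to 33.5 M. In each of the 4 fluoxetine comparisons and both lithium comparisons in females the difference in depth had an exact permutation p = 0.0079 (two-sided, BH-adjusted p = 0.021), the smallest that 5 libraries against 5 allow. In lithium males it had exact p = 0.29 among libraries labelled HT and 0.94 in WT.

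**Figure D1:**
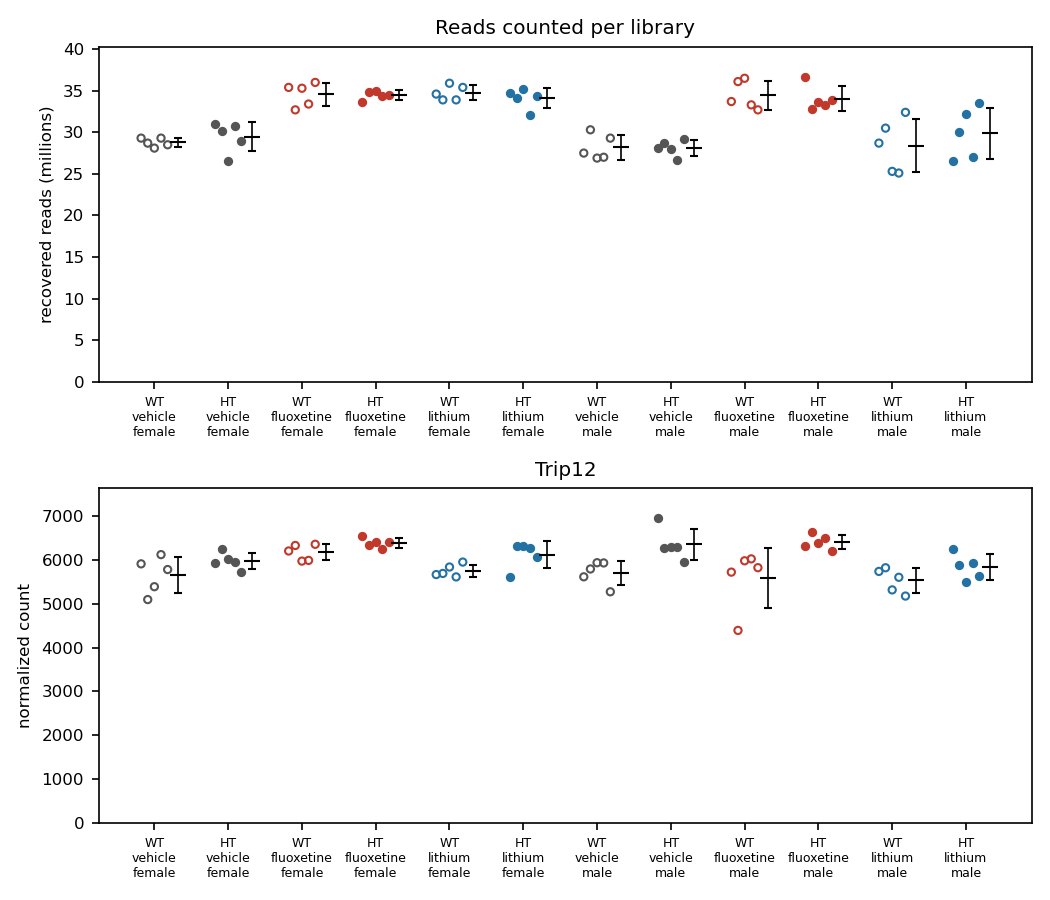
Recovered reads and normalized counts of Trip12 for the 12 groups of 5 libraries (filled points HT, open points WT, grey vehicle, red fluoxetine, blue lithium, bars mean ± SD). Every fluoxetine library lies above the vehicle range of 26.6 to 31 M reads, and Trip12 is not lower in libraries labelled HT.

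After each gene, parentheses give its log2 fold change ± SE, limma's adjusted p (Benjamini-Hochberg over 17804 genes), and how many libraries of the first-named group lay on that side of the mean of their reference group. Each group held 5 libraries. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Of a gene list, the text gives how many measured members rose and fell; the others were not called. The lists, tests and contrasts were fixed before the data were examined, except where the text says otherwise. The labels name neither animals nor litters, so p-values measure the spread among these samples.

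Trip12 encodes a HECT-domain E3 ubiquitin ligase (ENSMUSG00000026219, GRCm38 chromosome 1, 84721189 to 84840516, minus strand). Libraries labelled HT had a higher mean of Trip12 than WT libraries in each treatment and sex. Under vehicle, females labelled HT had 5979 ± 188 normalized counts of Trip12 (SD, n = 5) against 5664 ± 413 in WT. Males labelled HT had 6358 ± 365 against 5714 ± 278. The Trip12 difference was a log2 fold change of 0.08 ± 0.05 (SE, limma adjusted p = 0.91, higher in 5 of 5 libraries) in females. In males it was a log2 fold change of 0.15 ± 0.05 (SE, limma adjusted p = 0.34, higher in 5 of 5 libraries). Over vehicle, fluoxetine and lithium together, in a contrast added after the data were seen, Trip12 rose with a log2 fold change of 0.11 ± 0.02 (SE, limma adjusted p = 0.0014, higher in 28 of 30 libraries). The labels do not say what the allele is or which part of the gene it alters, and values per gene cannot show it. Every direction between genotypes given here therefore rests on the labels, which the Trip12 reads neither bear out nor contradict while the allele is unknown.

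The sexes were compared in WT vehicle mice to check the labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty rose in males: Ddx3y had 1691 ± 222 normalized counts in males (SD, n = 5) and 0.398 ± 0.546 in females. Kdm5d (917 ± 196) and Uty (499.5 ± 54.7) were read in males and were 0 in every WT vehicle female library. Xist, the RNA of X inactivation, had 22380 ± 4000 normalized counts in females and 1.04 ± 0.0587 in males. Of the genes that escape X inactivation, Eif2s3x (-0.55 ± 0.04, adjusted p = 9.2e-14, 5 of 5), Kdm6a (-0.42 ± 0.08, adjusted p = 0.003, 5 of 5) and Ddx3x (-0.30 ± 0.07, adjusted p = 0.047, 5 of 5) fell in males. Limma called 6 genes higher and 4 lower in males. The Y-linked list was higher and the escape list lower, and both list calls hold with an estimated correlation (adjusted p = 2.4e-24 and adjusted p = 8.2e-13). Ddx3x lost its call without at least 1 library.

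Gene lists were tested against all other genes with camera at its preset correlation of 0.01, and that test called as many lists in random splits of the libraries as in several real comparisons. With an estimated correlation between genes 6 calls hold in the comparisons of genotypes and of drugs with vehicle, within a sex or averaged over the sexes. In males labelled HT under fluoxetine these were striatal markers, cholesterol synthesis genes and glucocorticoid-induced genes. The others were glucocorticoid-induced genes under lithium in WT males and in WT with the sexes averaged, and interferon-induced genes between genotypes in lithium males. Outside these comparisons the calls that hold are the 2 sex lists, striatal markers in the interaction of genotype and fluoxetine in males, and glucocorticoid-induced genes under lithium averaged over genotypes and sexes. An exact permutation of each list's mean score within sex (two-sided, BH-adjusted over the lists) was added after those splits were seen. In a single sex the smallest possible p is 0.0079, and a list could pass only where several reached it together, so that 0 passed there decides little. With 63504 permutations it passed 22 lists over the sexes averaged.

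The first comparison asks what the genotype changes in untreated cortex. Under vehicle, with the sexes averaged, libraries labelled HT had more RNA of Pde10a (0.74 ± 0.16, adjusted p = 0.028, 9 of 10), a phosphodiesterase of striatal medium spiny neurons. Alox12b (0.69 ± 0.14, adjusted p = 0.016, 10 of 10), a lipoxygenase, and Rasgrp2 (0.43 ± 0.09, adjusted p = 0.017, 9 of 10), an exchange factor for Ras and Rap proteins, also rose. Socs2 (-0.30 ± 0.05, adjusted p = 0.0085, 10 of 10), a negative regulator of growth hormone and cytokine signalling, and Myl4 (-0.36 ± 0.07, adjusted p = 0.013, 10 of 10), a myosin light chain, fell. So did Npnt (-0.28 ± 0.06, adjusted p = 0.024, 10 of 10), an extracellular matrix protein, and Mtfp1 (-0.17 ± 0.03, adjusted p = 0.016, 10 of 10), a mitochondrial fission protein. Within females Socs2 fell, with a log2 fold change of -0.42 ± 0.07 (SE, limma adjusted p = 0.0092, lower in 5 of 5 libraries). Within males Mtfp1 fell, with a log2 fold change of -0.25 ± 0.05 (SE, limma adjusted p = 0.028, lower in 5 of 5 libraries).

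Striatal markers lay higher in vehicle libraries labelled HT: of 17 measured striatal markers 1 rose and 0 fell, or 14 and 0 adjusted over the list alone. Its mean log2 fold change was 0.84 (higher in 6 of 10 libraries, adjusted p = 0.2 with an estimated correlation and 0.19 by exact permutation). In the same comparison olfactory bulb markers had a mean of -0.69 and myelinating oligodendrocyte markers 0.22, with 0 members called. In males alone, of 17 measured striatal markers 0 rose and 0 fell, or 17 and 0 adjusted over the list alone. The list's mean log2 fold change was 1.41 (higher in 4 of 5 libraries, adjusted p = 0.071 with an estimated correlation and 0.17 by exact permutation). The striatal score of single libraries averaged 1.37 in vehicle males labelled HT and -0.036 in WT (exact permutation p = 0.04, BH-adjusted p = 0.18). Their length slope, a measure of how read numbers follow gene length, was also higher, 0.0156 against -0.0158 (exact permutation p = 0.0079, the smallest possible). Of 19 measured endothelial and mural cell markers 0 rose and 0 fell, or 0 and 3 adjusted over the list alone. Over all measured members the mean log2 fold change was -0.15 (lower in 8 of 10 libraries, adjusted p = 0.37 with an estimated correlation and 0.19 by exact permutation).

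Limma called 18 genes higher and 9 lower in vehicle libraries labelled HT with the sexes averaged. It called 1 in females and 2 in males, all lower, where 1057 and 1634 genes had an unadjusted p under 0.05. With olfactory bulb and striatal marker scores as covariates 5 were called with the sexes averaged, and Pde10a had a log2 fold change of 0.36 (adjusted p = 0.29, not called). DESeq2 on the recovered reads called 3, 34 and 62 genes in females, males and both, and edgeR 1, 13 and 31. Leaving out each library in turn gave 0 (without HT vehicle female replicate 1) to 3 genes (without WT vehicle female replicate 4) in females, with 7 of 10 libraries moving the count by more than 1.5 times. In males it gave 0 (without HT vehicle male replicate 2) to 77 (without HT vehicle male replicate 1), moved by 10 of 10. With the sexes averaged it gave 11 (without HT vehicle male replicate 4) to 83 (without HT vehicle male replicate 1), moved by 9 of 20. Socs2 in females and Mtfp1 in males lost their call without at least 1 library, and so did Pde10a, Rasgrp2 and Npnt in the averaged comparison. In simulated vehicle males limma called 152 genes, with 21 of 67 changed 1.2-fold and 65 of 66 changed 2-fold. With 2 real calls the cut is stricter and may miss more.

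**Figure D2:**
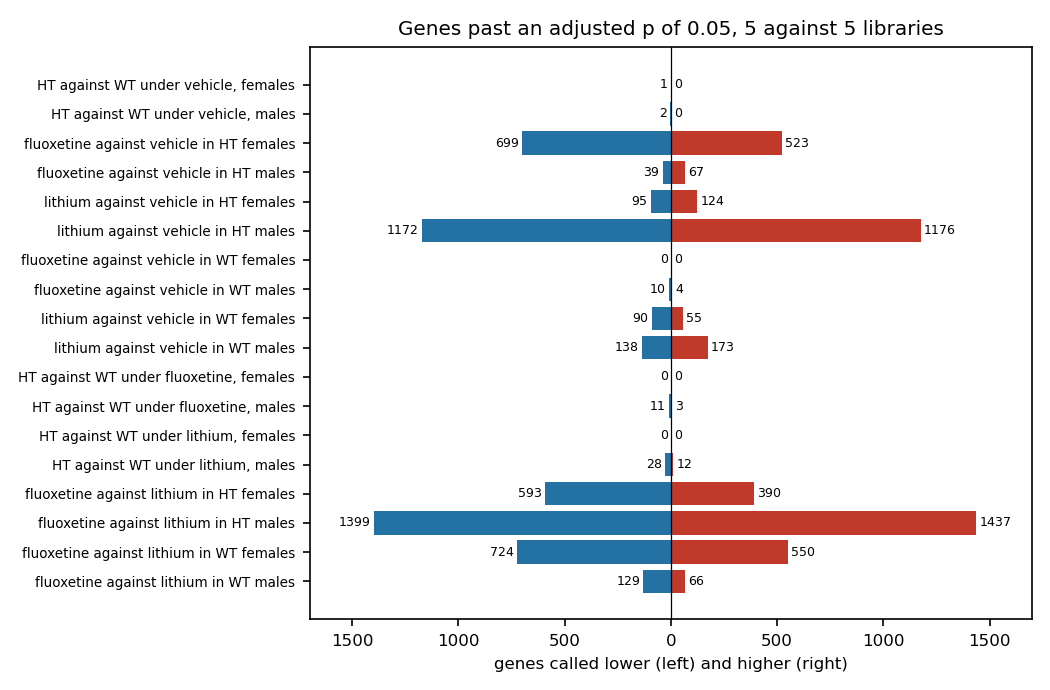
Number of genes called lower (left, blue) and higher (right, red) by limma at an adjusted p of 0.05 in each comparison of 5 libraries against 5. The longest bars, 1437 and 1399 genes, belong to fluoxetine against lithium in males labelled HT, and each genotype comparison has at most 40 genes.

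The next comparisons ask how 3 weeks of fluoxetine changed the cortex of mice labelled HT. With the sexes averaged, genes of cholesterol synthesis fell: of 26 measured cholesterol synthesis genes 1 rose and 14 fell, or 1 and 19 adjusted over the list alone. Members had a mean log2 fold change of -0.22 (lower in 10 of 10 libraries, adjusted p = 0.32 with an estimated correlation and 0.0049 by exact permutation). Insig1 (-0.38 ± 0.05, adjusted p = 1.2e-06, 10 of 10) and Stard4 (-0.39 ± 0.06, adjusted p = 5.3e-06, 10 of 10), targets of the sterol-sensing factor SREBP, were among them. Among the largest rises were Bc1 (1.28 ± 0.22, adjusted p = 0.00017, 10 of 10), a small non-coding brain RNA, and Nostrin (0.74 ± 0.11, adjusted p = 1e-05, 10 of 10), which traffics endothelial nitric oxide synthase. Tlr7 (0.73 ± 0.13, adjusted p = 2e-04, 10 of 10), an RNA receptor, and the zinc-finger transcription factor Zbtb16 (0.70 ± 0.09, adjusted p = 1.2e-06, 10 of 10) also rose. Gli1 (-0.69 ± 0.14, adjusted p = 0.00095, 10 of 10), a Hedgehog target, and the ribosomal protein gene Rpl10 (-0.78 ± 0.15, adjusted p = 5e-04, 10 of 10) fell.

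Nuclear-encoded genes of respiration and genes of the cytosolic ribosome fell with fluoxetine in libraries labelled HT, and mitochondrially encoded genes did not. Of 76 measured nuclear-encoded oxidative phosphorylation genes 0 rose and 39 fell, or 1 and 48 adjusted over the list alone. The mean over members was a log2 fold change of -0.15 (lower in 9 of 10 libraries, adjusted p = 0.33 with an estimated correlation and 0.011 by exact permutation). Of 13 measured mitochondrially encoded genes 6 rose and 0 fell, with a mean log2 fold change of 0.20 (adjusted p = 0.44 with an estimated correlation and 0.13 by exact permutation), or 2 rises and 0.07 after quantile normalization. Of 77 measured cytosolic ribosomal protein genes 0 rose and 40 fell, or 0 and 56 adjusted over the list alone. Averaged over members the log2 fold change was -0.21 (lower in 9 of 10 libraries, adjusted p = 0.32 with an estimated correlation and 0.0061 by exact permutation). These fluoxetine libraries were deeper, and in females their length slope was 0.0444 against -0.008 under vehicle (exact permutation p = 0.0079, BH-adjusted p = 0.03). With length and GC slopes as covariates 25 oxidative phosphorylation genes fell and 6 rose, 28 ribosomal protein genes fell, and the means shrank to -0.07 and -0.12. A depth covariate gave 44 and 51 falls, and 1 rise among the mitochondrially encoded genes. In WT the oxidative phosphorylation and ribosomal lists had means of -0.07 and -0.11 under fluoxetine with 0 members called, and 23 and 26 fell once the 2 libraries in doubt were left out (HT vehicle male replicate 1 and WT fluoxetine male replicate 2).

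Some postsynaptic genes rose with fluoxetine in libraries labelled HT: of 37 measured postsynaptic density genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone. The members' mean log2 fold change was 0.10 (higher in 9 of 10 libraries, adjusted p = 0.34 with an estimated correlation and 0.0066 by exact permutation). The called members included the scaffold genes Shank2 (0.28 ± 0.05, adjusted p = 0.00053, 10 of 10) and Homer1 (0.53 ± 0.11, adjusted p = 0.00092, 10 of 10). Of 19 measured glucocorticoid-induced genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone. Its mean log2 fold change was 0.31 (higher in 10 of 10 libraries, adjusted p = 0.32 with an estimated correlation and 0.011 by exact permutation). Of 19 measured endothelial and mural cell markers 5 rose and 0 fell, or 6 and 0 adjusted over the list alone. The list's mean log2 fold change was 0.13 (higher in 8 of 10 libraries, adjusted p = 0.48 with an estimated correlation and 0.14 by exact permutation). Among these were Flt1 (0.44 ± 0.06, adjusted p = 9.8e-07, 10 of 10), a receptor of vascular endothelial growth factor, and the glucose transporter gene Slc2a1 (0.45 ± 0.09, adjusted p = 0.00071, 10 of 10). Under a depth covariate 1 postsynaptic density gene, 3 glucocorticoid-induced genes and 4 endothelial and mural cell markers rose. Olfactory bulb markers had a mean of -0.91 over both sexes, and -0.83 in WT, with 0 of 12 called. In males alone, of 17 measured striatal markers 0 rose and 5 fell, or 0 and 17 adjusted over the list alone. Over all measured members the mean log2 fold change was -1.50 (lower in 5 of 5 libraries, adjusted p = 0.034 with an estimated correlation and 0.37 by exact permutation). Penk (-1.09 ± 0.22, adjusted p = 0.005, 5 of 5) and Adora2a (-1.90 ± 0.45, adjusted p = 0.029, 5 of 5) were among them. The striatal score of these males averaged -0.124 against 1.37 under vehicle (exact permutation p = 0.032, BH-adjusted p = 0.18).

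Limma called 837 genes higher and 987 lower with fluoxetine in libraries labelled HT over both sexes, 523 and 699 in females, and 67 and 39 in males. A depth covariate brought the averaged count to 778 (276 higher, 502 lower). With the recovered reads of each library thinned to 25.1 M reads it was 1667, of which 1585 were among the 1824. In females leaving out 1 library gave 545 (without HT fluoxetine female replicate 4) to 1345 (without HT fluoxetine female replicate 5), and 5 of 10 moved the count by more than 1.5 times. In males it gave 37 (without HT vehicle male replicate 4) to 270 (without HT vehicle male replicate 1), moved by 5 of 10, and Adora2a lost its call. The genes named here over both sexes kept their calls with each library left out in turn.

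Fluoxetine was next compared with vehicle in WT. With the sexes averaged, immediate early genes, which neuronal activity induces, were among the largest falls: Arc (-1.08 ± 0.23, adjusted p = 0.024, 9 of 10), Fos (-0.75 ± 0.17, adjusted p = 0.027, 10 of 10) and Nr4a1 (-0.74 ± 0.14, adjusted p = 0.005, 10 of 10). Arc (chromosome 15, 74669083 to 74672570) went from 4740 ± 1140 normalized counts (SD, n = 5) to 3351 ± 1430 in females, and from 5794 ± 1740 to 2059 ± 908 in males. Of 28 measured immediate early genes 0 rose and 4 fell, or 2 and 17 adjusted over the list alone. Members had a mean log2 fold change of -0.33 (lower in 9 of 10 libraries, adjusted p = 0.39 with an estimated correlation and 0.07 by exact permutation). Under a depth covariate that mean was -0.23 with 0 calls. Without the 2 libraries in doubt 12 fell and 1 rose. In libraries labelled HT under fluoxetine 4 of these genes rose and 3 fell, with a mean of -0.08 (adjusted p = 0.88 with an estimated correlation and 0.5 by exact permutation). Sox18 (0.70 ± 0.13, adjusted p = 0.005, 9 of 10), an endothelial transcription factor, Zbtb16 (0.46 ± 0.09, adjusted p = 0.012, 9 of 10), and the synaptic adhesion gene Lrfn2 (0.43 ± 0.08, adjusted p = 0.0048, 10 of 10) rose.

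Cholesterol synthesis genes fell in WT as well: of 26 measured 0 rose and 5 fell, or 0 and 20 adjusted over the list alone. The mean over members was a log2 fold change of -0.18 (lower in 10 of 10 libraries, adjusted p = 0.064 with an estimated correlation and 0.042 by exact permutation). Stard4 (-0.36 ± 0.06, adjusted p = 4e-04, 10 of 10) was among them. A depth covariate left 1 call, Stard4, and 15 fell without the 2 libraries in doubt. In WT males Sox18 (1.08 ± 0.18, adjusted p = 0.0036, 5 of 5) rose, and Arc (-1.55 ± 0.33, adjusted p = 0.035, 5 of 5) and Nr4a1 (-1.03 ± 0.20, adjusted p = 0.014, 5 of 5) fell. In WT females limma called 0 genes, with 1930 at an unadjusted p under 0.05, DESeq2 called 4 and edgeR 0. The smallest p there belonged to Pheta1 (-0.42 ± 0.08, adjusted p = 0.055, not called, 5 of 5). The length slope of WT females was 0.0476 under fluoxetine and -0.006 under vehicle (exact permutation p = 0.0079, BH-adjusted p = 0.03).

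Limma called 15 genes higher and 22 lower with fluoxetine in WT over both sexes, and 4 higher and 10 lower in WT males (28.6% higher), or 7 and 11 after quantile normalization (38.9%). With depth as a covariate 1 gene was called over both sexes and 1 in males. Leaving out 1 library gave 14 genes over both sexes (without WT fluoxetine male replicate 5) to 469 (without WT fluoxetine male replicate 2, whose length slope was -0.207), with 11 of 20 moving the count by more than 1.5 times. In males it gave 0 (without WT vehicle male replicate 4) to 34 (without WT fluoxetine male replicate 2), moved by 8 of 10, and each gene named for WT males lost its call at least once. In females the highest was 32 (without WT vehicle female replicate 1; 3 of 10 moved it). Over both sexes Arc and Fos lost their call without at least 1 library.

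**Figure D3:**
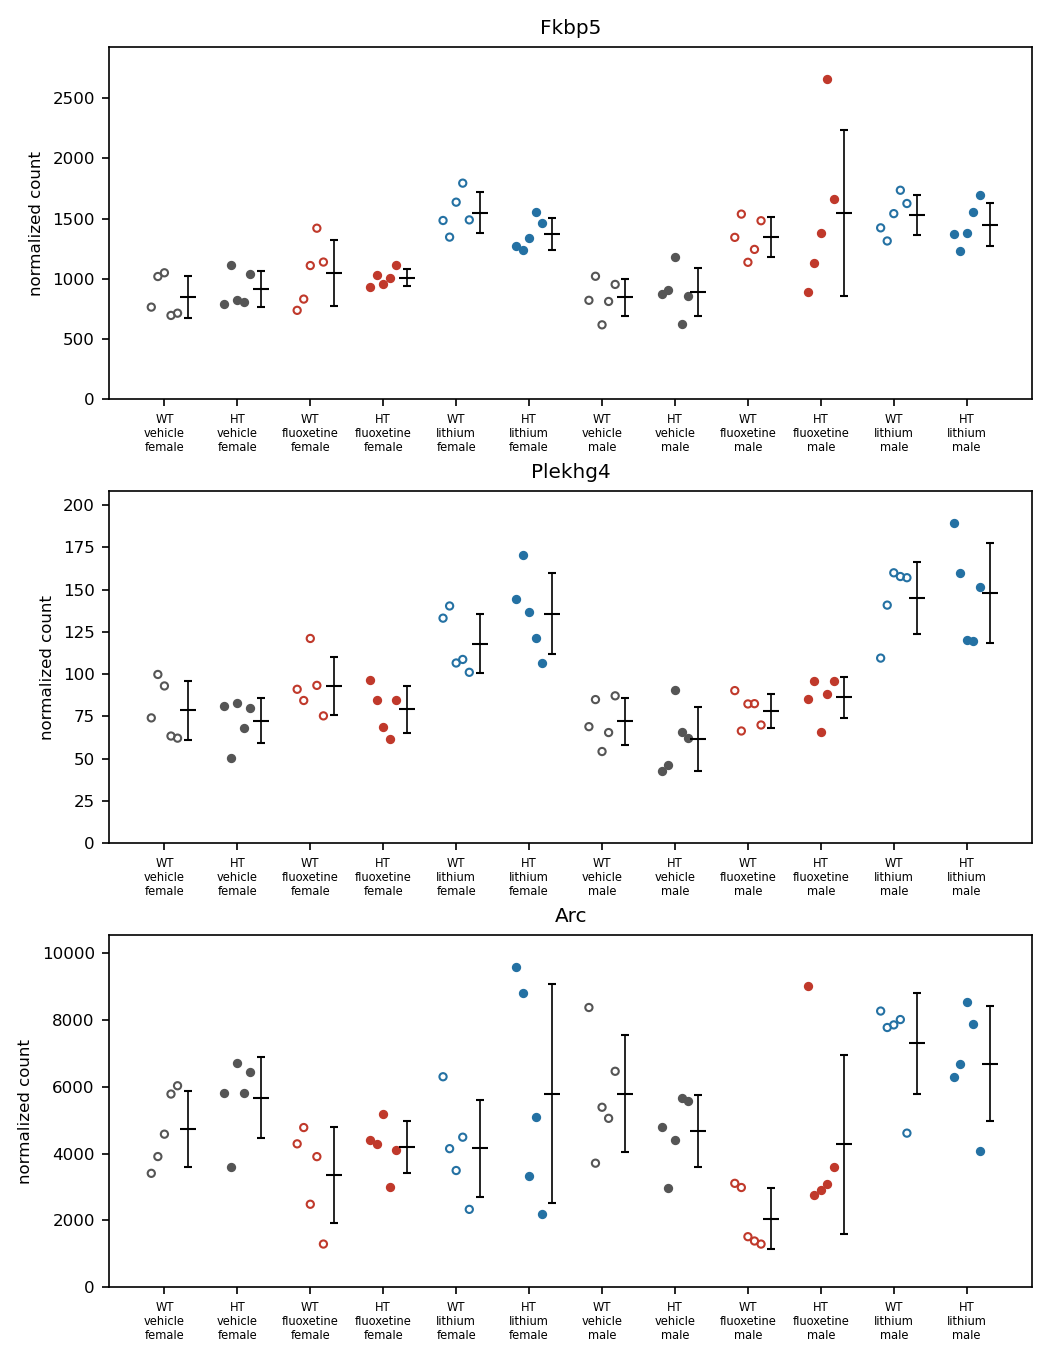
Normalized counts per library of Fkbp5, Plekhg4 and Arc in the 12 groups of 5 libraries (filled points HT, open points WT, grey vehicle, red fluoxetine, blue lithium, bars mean ± SD). Fkbp5 and Plekhg4 lie higher under lithium than under vehicle in both genotypes, and Arc lies lower under fluoxetine than under vehicle in WT.

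Lithium was compared with vehicle in mice labelled HT with the same question as fluoxetine. Among the largest rises over both sexes were Plekhg4 (1.09 ± 0.12, adjusted p = 1.8e-08, 10 of 10), which has a pleckstrin homology domain, and Lyve1 (1.07 ± 0.19, adjusted p = 0.00011, 10 of 10), a hyaluronan receptor. The heat shock genes Hspb1 (0.94 ± 0.14, adjusted p = 5.8e-06, 10 of 10) and Hspa1b (0.80 ± 0.14, adjusted p = 9.8e-05, 10 of 10) also rose, the latter with a near-identical copy that can share its reads. Plekhg4 (chromosome 8, 105373274 to 105382862) went from 72.6 ± 13.6 normalized counts (SD, n = 5) to 136 ± 24.2 in females, and from 61.6 ± 18.9 to 148 ± 29.4 in males. Genes of the unfolded protein response rose: of 22 measured unfolded protein response genes 18 rose and 0 fell, or 19 and 0 adjusted over the list alone. Averaged over members the log2 fold change was 0.28 (higher in 10 of 10 libraries, adjusted p = 0.093 with an estimated correlation and 0.0043 by exact permutation). Atf4 (0.33 ± 0.05, adjusted p = 5.5e-06, 10 of 10), Pdia4 (0.46 ± 0.07, adjusted p = 7.8e-06, 10 of 10) and Sdf2l1 (0.66 ± 0.10, adjusted p = 1e-05, 10 of 10) were among them. Of 19 measured glucocorticoid-induced genes 11 rose and 0 fell, or 11 and 0 adjusted over the list alone. The members' mean log2 fold change was 0.42 (higher in 10 of 10 libraries, adjusted p = 0.12 with an estimated correlation and 0.0025 by exact permutation). Fkbp5 (0.66 ± 0.12, adjusted p = 0.00013, 10 of 10), a co-chaperone of the glucocorticoid receptor, and Zbtb16 (0.53 ± 0.09, adjusted p = 6.7e-05, 9 of 10) belong to that list.

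The largest falls with lithium in libraries labelled HT included genes of striatal signalling: the dopamine receptors Drd2 (-1.67 ± 0.44, adjusted p = 0.0065, 10 of 10) and Drd1 (-0.94 ± 0.22, adjusted p = 0.0025, 10 of 10), and the adenosine receptor Adora2a (-1.39 ± 0.32, adjusted p = 0.002, 10 of 10). Of 17 measured striatal markers 0 rose and 14 fell, or 0 and 17 adjusted over the list alone. Its mean log2 fold change was -1.10 (lower in 10 of 10 libraries, adjusted p = 0.38 with an estimated correlation and 0.031 by exact permutation). The striatal score of males was -0.326 under lithium and 1.37 under vehicle (exact permutation p = 0.032, BH-adjusted p = 0.18). Of 26 measured cholesterol synthesis genes 0 rose and 9 fell, or 0 and 13 adjusted over the list alone. The list's mean log2 fold change was -0.16 (lower in 9 of 10 libraries, adjusted p = 0.39 with an estimated correlation and 0.042 by exact permutation). Of 23 measured myelinating oligodendrocyte markers 0 rose and 11 fell, or 0 and 17 adjusted over the list alone. Over all measured members the mean log2 fold change was -0.38 (lower in 9 of 10 libraries, adjusted p = 0.69 with an estimated correlation and 0.054 by exact permutation). Of 76 measured nuclear-encoded oxidative phosphorylation genes 22 rose and 0 fell, or 27 and 1 adjusted over the list alone. Members had a mean log2 fold change of 0.10 (higher in 9 of 10 libraries, adjusted p = 0.69 with an estimated correlation and 0.047 by exact permutation). With depth as a covariate 4 of them rose, and after quantile normalization 17 rose and 1 fell.

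Limma called 1324 genes higher and 1271 lower with lithium in libraries labelled HT over both sexes, 1176 and 1172 in males, and 124 and 95 in females. In females leaving out 1 library gave 31 (without HT lithium female replicate 2) to 456 (without HT lithium female replicate 5), with 7 of 10 moving the count by more than 1.5 times, and with depth as a covariate it was 88. The genes named here kept their calls over both sexes with each library left out in turn. With olfactory bulb and striatal marker scores as covariates the fold change of Drd2 was 0.01, and camera's adjusted p for the myelinating oligodendrocyte markers went from 1.2e-07 to 0.52. The striatal score takes in Drd2 itself, so for Drd2 the covariate removes the change by construction.

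In WT mice glucocorticoid-induced genes were higher under lithium than under vehicle: of 19 measured glucocorticoid-induced genes 13 rose and 0 fell, or 16 and 0 adjusted over the list alone. The mean over members was a log2 fold change of 0.47 (higher in 10 of 10 libraries, adjusted p = 0.0087 with an estimated correlation and 0.0012 by exact permutation). Fkbp5 (0.87 ± 0.12, adjusted p = 1.3e-05, 10 of 10), on chromosome 17 (28399094 to 28517527), rose. It went from 850 ± 171 normalized counts (SD, n = 5) to 1551 ± 171 in females, and from 846 ± 155 to 1529 ± 165 in males. Plekhg4 (0.80 ± 0.12, adjusted p = 5.4e-05, 10 of 10) and the sulfotransferase gene Sult1a1 (0.85 ± 0.17, adjusted p = 0.0011, 10 of 10) rose as well. Among the largest falls were Aplnr (-1.08 ± 0.30, adjusted p = 0.022, 9 of 10), the apelin receptor, and Kdr (-0.56 ± 0.09, adjusted p = 0.00012, 10 of 10), a receptor of vascular endothelial growth factor. Casq2 (-0.75 ± 0.14, adjusted p = 0.00064, 10 of 10), a calsequestrin, fell too.

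Other lists moved with lithium in WT. Of 26 measured cholesterol synthesis genes 0 rose and 13 fell, or 0 and 17 adjusted over the list alone. Averaged over members the log2 fold change was -0.18 (lower in 10 of 10 libraries, adjusted p = 0.18 with an estimated correlation and 0.0012 by exact permutation). Of 22 measured unfolded protein response genes 8 rose and 0 fell, or 14 and 0 adjusted over the list alone. The members' mean log2 fold change was 0.16 (higher in 9 of 10 libraries, adjusted p = 0.21 with an estimated correlation and 0.009 by exact permutation). Of 76 measured nuclear-encoded oxidative phosphorylation genes 6 rose and 0 fell, or 18 and 0 adjusted over the list alone. Its mean log2 fold change was 0.11 (higher in 9 of 10 libraries, adjusted p = 0.6 with an estimated correlation and 0.029 by exact permutation). When depth was a covariate 13 cholesterol synthesis genes fell, 4 unfolded protein response genes rose, and 0 oxidative phosphorylation genes rose, with a mean of 0.06. In WT males alone, of 19 measured glucocorticoid-induced genes 9 rose and 0 fell, or 13 and 0 adjusted over the list alone. The list's mean log2 fold change was 0.55 (higher in 5 of 5 libraries, adjusted p = 0.031 with an estimated correlation and 0.077 by exact permutation).

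Limma called 438 genes higher and 376 lower with lithium in WT over both sexes, 173 and 138 in males, and 55 and 90 in females. With depth as a covariate 456 were called over both sexes and 5 in females. Leaving out 1 library gave 11 genes (without WT vehicle female replicate 1) to 322 (without WT lithium female replicate 5) in females, and 9 of 10 moved the count by more than 1.5 times. In males it gave 50 (without WT lithium male replicate 4) to 447 (without WT lithium male replicate 1), moved by 7 of 10. Aplnr over both sexes lost its call without at least 1 library.

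**Figure D4:**
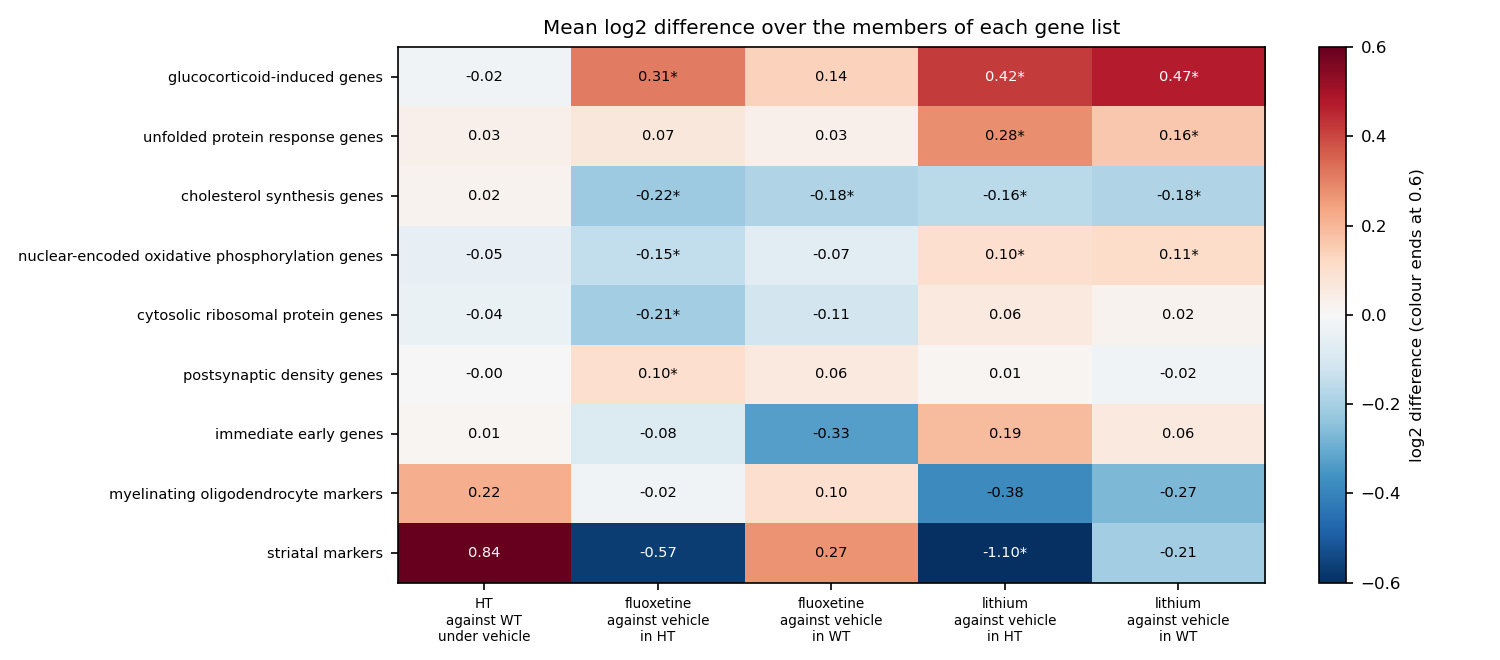
Mean log2 fold change over the members of gene lists (colour and printed value) between genotypes under vehicle and for each drug against vehicle, averaged over the sexes. An asterisk marks a BH-adjusted p under 0.05 in the exact permutation of list scores: glucocorticoid-induced genes lie higher (0.42 and 0.47) and cholesterol synthesis genes lower (-0.16 and -0.18) under lithium in libraries labelled HT and in WT.

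Whether the genotypes differ under a drug was tested next. Among fluoxetine males, libraries labelled HT had more RNA of the neuronal adhesion gene Cntn3 (0.43 ± 0.09, adjusted p = 0.049, 5 of 5). They had less of Mrps28 (-0.52 ± 0.11, adjusted p = 0.033, 5 of 5), of the mitochondrial ribosome, and Sil1 (-0.47 ± 0.10, adjusted p = 0.033, 5 of 5), an exchange factor of the chaperone BiP. Among lithium males, libraries labelled HT had more of the interferon transcription factor Irf7 (0.80 ± 0.19, adjusted p = 0.045, 5 of 5), and less of Nrn1 (-0.43 ± 0.09, adjusted p = 0.03, 5 of 5), neuritin, and Myl4 (-0.44 ± 0.10, adjusted p = 0.03, 5 of 5). Among these lithium males, of 17 measured interferon-induced genes 1 rose and 0 fell, or 6 and 0 adjusted over the list alone. Over all measured members the mean log2 fold change was 0.37 (higher in 5 of 5 libraries, adjusted p = 0.029 with an estimated correlation and 0.31 by exact permutation). Among fluoxetine males, of 77 measured cytosolic ribosomal protein genes 0 rose and 0 fell, or 0 and 66 adjusted over the list alone. Members had a mean log2 fold change of -0.24 (lower in 5 of 5 libraries, adjusted p = 0.21 with an estimated correlation and 0.23 by exact permutation). The length slope was 0.0248 in the fluoxetine males labelled HT and -0.0332 in WT (exact permutation p = 0.016, BH-adjusted p = 0.043); the WT mean rests on WT fluoxetine male replicate 2 at -0.207, with the other 4 at 0.006 to 0.014. In lithium females, of 12 measured olfactory bulb markers 0 rose and 0 fell, or 0 and 9 adjusted over the list alone. The mean over members was a log2 fold change of -2.18 (lower in 3 of 5 libraries, adjusted p = 0.61 with an estimated correlation and 0.48 by exact permutation).

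Limma called 3 genes higher and 11 lower in fluoxetine males labelled HT, and 12 higher and 28 lower in lithium males. Leaving out 1 library gave 1 (without HT fluoxetine male replicate 2) to 49 (without WT fluoxetine male replicate 1) under fluoxetine, moved by 8 of 10. Under lithium it gave 0 (without HT lithium male replicate 1) to 118 (without HT lithium male replicate 4), moved by 9 of 10, and each gene named for either drug lost its call at least once. In fluoxetine females limma, DESeq2 and edgeR called 0 genes, with 728 at an unadjusted p under 0.05. In lithium females limma called 0, with 1717 at an unadjusted p under 0.05, DESeq2 called 25 and edgeR 0. Without HT lithium female replicate 5 limma called 20 there.

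The interaction of genotype and drug, the direct test of a different response between libraries labelled HT and WT, had 0 genes by limma and by edgeR in either sex and for both drugs. At an unadjusted p under 0.05 there were 646 genes for fluoxetine in females, 636 in males and 786 averaged, and 1125, 2207 and 996 for lithium. DESeq2 called 2, 0 and 1 for fluoxetine, and 1, 1 and 0 for lithium. For a single gene, a response called in libraries labelled HT and not in WT is therefore not shown by limma to differ between the genotypes. Of the lists, striatal markers had an interaction with fluoxetine in males, with a mean log2 difference of -1.80 (adjusted p = 0.017 with an estimated correlation and 0.045 by fry). In those males the striatal score was 1.37 under vehicle and -0.124 under fluoxetine in libraries labelled HT, and -0.036 and 0.264 in WT. Without HT vehicle male replicate 1 limma called 11 genes for fluoxetine in males, and without WT lithium male replicate 1 it called 1 for lithium in males.

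Sex was tested in the same way. The interaction of sex and genotype under vehicle had 0 genes by limma and by edgeR, with 1093 at an unadjusted p under 0.05, and 1 by DESeq2. The interactions of sex with fluoxetine and with lithium had 0 by limma and by edgeR in libraries labelled HT, with 1214 and 2117 at an unadjusted p under 0.05, and 5 and 3 by DESeq2. In WT limma and edgeR called 0, with 1222 and 2218 at an unadjusted p under 0.05, and DESeq2 2 and 2. Without WT vehicle female replicate 4 limma called 146 genes for sex by lithium in WT. Without HT vehicle male replicate 1 it called 12 for sex by fluoxetine in libraries labelled HT, and without HT lithium male replicate 4 it called 2 for sex by lithium there.

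The drugs were also set against each other. In WT males, of 28 measured immediate early genes 0 rose and 8 fell, or 0 and 18 adjusted over the list alone. Averaged over members the log2 fold change was -0.59 (lower in 5 of 5 libraries, adjusted p = 0.095 with an estimated correlation). Arc (-1.90 ± 0.33, adjusted p = 0.0013, 5 of 5) and Nr4a1 (-1.07 ± 0.20, adjusted p = 0.0026, 5 of 5) were among them. Plekhg4 (-0.77 ± 0.17, adjusted p = 0.0039, 5 of 5) was lower under fluoxetine in females labelled HT. In males labelled HT Hspb1 (-0.84 ± 0.20, adjusted p = 0.0026, 5 of 5) and Atf4 (-0.49 ± 0.07, adjusted p = 1.1e-05, 5 of 5) were lower under fluoxetine than under lithium, and Rims1 (0.62 ± 0.10, adjusted p = 8.7e-05, 5 of 5), which organises synaptic vesicle release, was higher. In these males, of 17 measured interferon-induced genes 0 rose and 7 fell, or 0 and 10 adjusted over the list alone. The members' mean log2 fold change was -0.40 (lower in 5 of 5 libraries, adjusted p = 0.17 with an estimated correlation). In WT females Kdr (0.70 ± 0.13, adjusted p = 0.00082, 5 of 5) was higher under fluoxetine and Etnppl (-1.48 ± 0.32, adjusted p = 0.0035, 5 of 5) lower. Of 76 oxidative phosphorylation genes, 44 fell in females and 41 in males labelled HT, 47 in WT females and 0 in WT males (adjusted over the list alone 54, 45, 58 and 0). That list had adjusted p = 0.068, 0.29 and 0.14 with an estimated correlation in the first 3 groups. The length slope of fluoxetine females was 0.0444 against 0.0018 under lithium in libraries labelled HT (exact permutation p = 0.016), and 0.0476 against -0.029 in WT (exact permutation p = 0.0079).

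Limma called 390 genes higher and 593 lower under fluoxetine than under lithium in females labelled HT, 1437 and 1399 in males labelled HT, 550 and 724 in WT females, and 66 and 129 in WT males. With depth as a covariate 0 were called in WT males. In that group leaving out 1 library gave 37 (without WT lithium male replicate 4) to 426 (without WT fluoxetine male replicate 2), moved by 7 of 10. The lowest counts elsewhere were 390 without HT fluoxetine female replicate 4, 1740 without HT fluoxetine male replicate 4 and 669 without WT lithium female replicate 2. Of 10 libraries each, 3, 1 and 5 moved them by more than 1.5 times. The genes named for the drug comparison kept their calls with each library left out in turn.

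Whether a drug reverses the genotype difference was asked across genes, which are not independent replicates. The log2 fold changes of genotype (libraries labelled HT against WT under vehicle) and of the drug in libraries labelled HT share the HT vehicle libraries. That alone gives a correlation of -0.49 (-0.77 to -0.17 in simulated groups with no effect). The observed values were -0.47 and -0.31 for fluoxetine in females and males, and -0.46 and -0.53 for lithium. Their covariances were -0.027, -0.0211, -0.0266 and -0.043, and less the simulated -0.0236 they left -0.00341, 0.00246, -0.003 and -0.0194. With the vehicle libraries split between the contrasts the correlations were -0.05, 0.07, -0.05 and -0.13. Of the 2 genes called between vehicle males, both lower in libraries labelled HT, 1 rose with lithium, a comparison that uses the same vehicle libraries.

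Whether fluoxetine and lithium act on the same genes was asked the same way. The responses correlated at 0.48 in females and 0.43 in males labelled HT, and at 0.35 and 0.52 in WT, where shared vehicle libraries alone give 0.48 (0.18 to 0.72). The covariances were 0.0311, 0.0346, 0.0209 and 0.0391, and less the simulated 0.0236 they left 0.00752, 0.0111, -0.00268 and 0.0156. All lie within the simulated range of 0.00814 to 0.0478. Split vehicle libraries gave correlations of 0.09, 0.06, -0.07 and 0.18. In females labelled HT 32 genes rose with both drugs and 25 fell with both. In males labelled HT these were 40 and 27, and in WT males 2 and 2. Both calls rest on the same vehicle libraries, so these counts do not show a shared action. In WT females fluoxetine had 0 calls by limma to share.

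**Figure D5:**
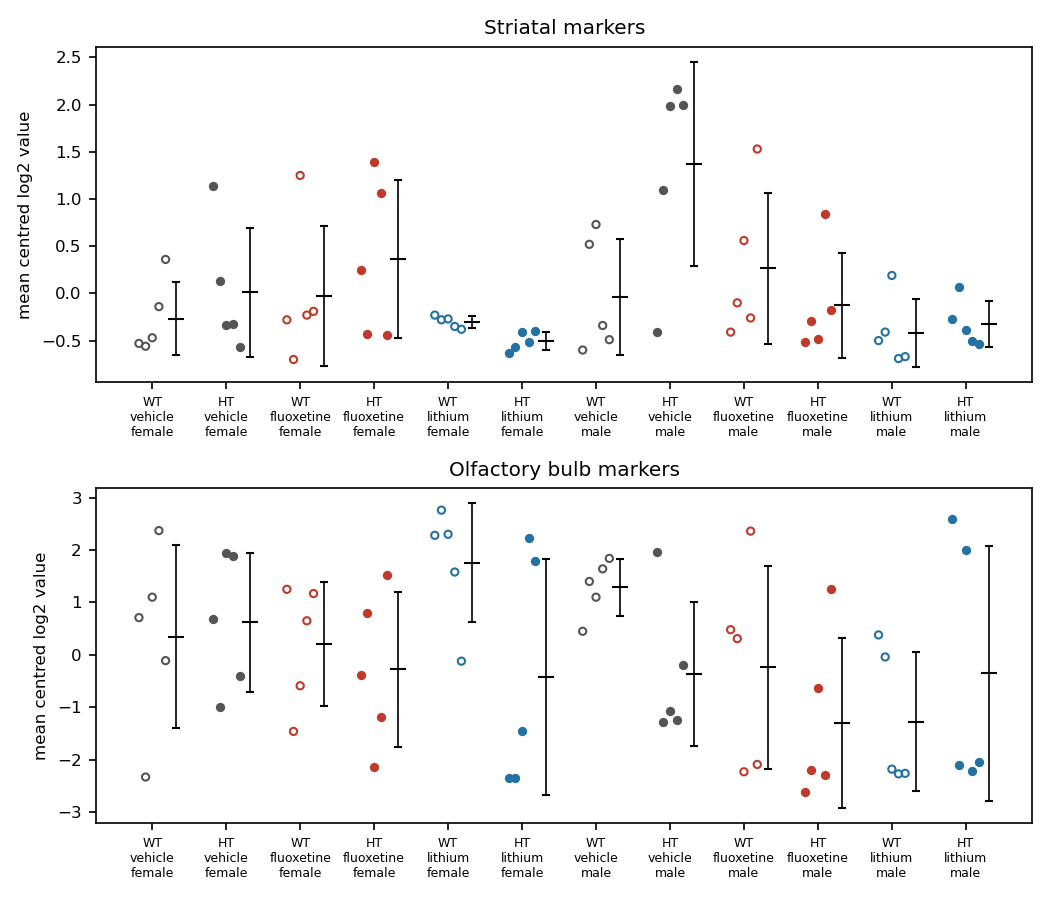
Striatal and olfactory bulb marker scores of each library (mean centred log2 value of the list) in the 12 groups of 5 libraries (filled points HT, open points WT, grey vehicle, red fluoxetine, blue lithium, bars mean ± SD). The highest striatal mean, 1.37, is that of vehicle males labelled HT, whose libraries run from -0.41 to 2.17.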

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

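The test of the depth difference between sexes and the choice of Fkbp5, Plekhg4 and Arc for values per library came after their results were seen. Single libraries far from the other 4 of their group were looked for in 120 groups of values, by the gap to the nearest library over the group's range (Dixon's critical value 0.71). Chance alone marks about 5% of groups, and 9 were marked.

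HT fluoxetine male replicate 1, of the libraries labelled HT, held 36.6 M reads, the other 4 of its group 32.8 to 33.9. The striatal score was 1.25 in WT fluoxetine female replicate 3 (others -0.7 to -0.19) and 0.84 in HT fluoxetine male replicate 4 (others -0.51 to -0.18). HT vehicle male replicate 1 had a length slope of 0.044 (others 0.001 to 0.012) and a GC slope of -2.61 (others 0.16 to 0.78). WT fluoxetine male replicate 2 had a length slope of -0.207 (others 0.006 to 0.014) and 4394 normalized counts of Trip12 (others 5726 to 6029). Arc had 9014 normalized counts in HT fluoxetine male replicate 1 (others 2749 to 3587) and 4610 in WT lithium male replicate 5 (others 7766 to 8258).

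Lithium libraries exceeded vehicle libraries in depth by 5.29 M reads in females and 0.96 M in males, and these differences differed by 4.33 M (permutation p = 0.0094, 100000 permutations of sex within genotype and treatment). In each genotype the lithium females were deeper than the vehicle females with an exact permutation p = 0.0079.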

How the results depend on the processing

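The tests chosen after the result was seen were edgeR, the covariates for depth, for length and GC slopes and for marker scores, the removal of 2 libraries together, the exact permutation of list scores, the thinned reads and the 3 contrasts averaged over all arms. HT stands for libraries labelled HT, in which Trip12 reads were not lower, and drugs compared for fluoxetine against lithium. An entry here is a named gene in a contrast where the rule picked it, whether called there or not. With a pseudocount of 0.5, 743 entries were kept on their side of the threshold and 0 gained or lost a call. Kept entries were 734 after TMM rescaling, 741 with no filter, 723 after quantile normalization and 718 with edgeR. Called entries among them kept their direction, and entries not called may have changed sign. Depth as a covariate weakened 134 entries and a fit on only the libraries compared 118, the second with fewer residual degrees of freedom. Genes called for both drugs in HT and for lithium in WT, averaged over sexes, stayed within 1.5 times with each library left out in turn. Numbers that moved by more than 1.5 times follow by setting, and the cause was not tested. Depth bounds what could be seen of low genes: 1491 genes had a mean under 10 normalized counts.

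DESeq2 on the recovered reads called 3 for genotype under vehicle, females, 34 for genotype under vehicle, males, 200 for fluoxetine in HT males, 409 for lithium in HT females, 4 for fluoxetine in WT females, 41 for fluoxetine in WT males, 373 for lithium in WT females, 127 for genotype under fluoxetine, males, 25 for genotype under lithium, females. Further values were 128 for genotype under lithium, males, 2 for genotype by fluoxetine, females, 1 for genotype by lithium, females, 1 for genotype by lithium, males, 62 for genotype under vehicle, averaged, 85 for fluoxetine in WT, averaged, 1 for genotype by fluoxetine, averaged, 1 for sex by genotype under vehicle, 5 for sex by fluoxetine in HT. Then came 3 for sex by lithium in HT, 2 for sex by fluoxetine in WT, 2 for sex by lithium in WT, 365 for drugs compared in WT males. The edgeR quasi-likelihood test on those reads, added later, called 13 for genotype under vehicle, males, 21 for genotype under lithium, males. With array weights limma called 0 for genotype under vehicle, females, 246 for genotype under vehicle, males, 2930 for fluoxetine in HT females, 786 for fluoxetine in HT males, 17 for fluoxetine in WT females, 335 for fluoxetine in WT males, 998 for lithium in WT females, 1103 for lithium in WT males, 92 for genotype under lithium, females. Further values were 0 for genotype under lithium, males, 48 for genotype by fluoxetine, males, 3 for genotype by lithium, males, 146 for genotype under vehicle, averaged, 3969 for fluoxetine in HT, averaged, 1105 for fluoxetine in WT, averaged, 1442 for lithium in WT, averaged, 5 for genotype by fluoxetine, averaged, 21 for sex by fluoxetine in HT. Then came 1 for sex by fluoxetine in WT, 858 for sex by lithium in WT, 4131 for drugs compared in WT females, 680 for drugs compared in WT males, 1379 for genotype averaged over all, 5111 for fluoxetine averaged over all.

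A fit on only the libraries compared called 0 for genotype under vehicle, females, 0 for genotype under vehicle, males, 3 for fluoxetine in HT males, 7 for lithium in HT females, 770 for lithium in HT males, 7 for fluoxetine in WT males, 16 for lithium in WT females, 1027 for lithium in WT males, 0 for genotype under fluoxetine, males. Further values were 0 for genotype under lithium, males, 4 for genotype under vehicle, averaged, 1700 for lithium in HT, averaged, 12 for fluoxetine in WT, averaged, 354 for drugs compared in HT females, 1700 for drugs compared in HT males, 21 for drugs compared in WT males. With 2 surrogate variables the numbers were 3 for genotype under vehicle, females, 8 for genotype under vehicle, males, 1996 for fluoxetine in HT females, 226 for fluoxetine in HT males, 462 for lithium in HT females, 1 for fluoxetine in WT females, 281 for lithium in WT females, 222 for genotype under fluoxetine, males, 59 for genotype under vehicle, averaged. Further values were 63 for fluoxetine in WT, averaged, 1540 for lithium in WT, averaged, 1 for genotype by fluoxetine, averaged, 1500 for drugs compared in HT females, 562 for drugs compared in WT males, 1655 for genotype averaged over all. With depth as a covariate they were 14 for fluoxetine in HT males, 88 for lithium in HT females, 2 for fluoxetine in WT females, 1 for fluoxetine in WT males, 5 for lithium in WT females, 778 for fluoxetine in HT, averaged, 1 for fluoxetine in WT, averaged, 456 for lithium in WT, averaged, 0 for drugs compared in WT males. Further values were 491 for fluoxetine averaged over all, 2466 for lithium averaged over all.

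With length and GC slopes as covariates they were 25 for genotype under vehicle, males, 451 for fluoxetine in HT females, 281 for fluoxetine in HT males, 515 for lithium in HT females, 1 for fluoxetine in WT females, 42 for fluoxetine in WT males, 348 for lithium in WT females, 736 for lithium in WT males, 2 for genotype under fluoxetine, males. Further values were 52 for genotype under vehicle, averaged, 1 for sex by lithium in WT, 803 for drugs compared in WT females, 648 for drugs compared in WT males. With olfactory bulb and striatal marker scores as covariates they were 2 for genotype under vehicle, females, 0 for genotype under vehicle, males, 1862 for fluoxetine in HT females, 339 for lithium in HT females, 1362 for lithium in HT males, 109 for lithium in WT males, 67 for genotype under fluoxetine, males, 62 for genotype under lithium, males, 5 for genotype under vehicle, averaged. Further values were 1642 for lithium in HT, averaged, 1236 for lithium in WT, averaged, 1 for sex by lithium in WT, 111 for drugs compared in WT males, 1574 for genotype averaged over all. Without HT vehicle male replicate 1 and WT fluoxetine male replicate 2 together they were 89 for genotype under vehicle, males, 479 for fluoxetine in HT males, 430 for lithium in HT females, 35 for fluoxetine in WT females, 42 for fluoxetine in WT males, 344 for lithium in WT females, 564 for lithium in WT males, 1 for genotype under fluoxetine, males, 15 for genotype under lithium, females. Further values were 65 for genotype under lithium, males, 15 for genotype by fluoxetine, males, 12 for genotype by lithium, males, 104 for genotype under vehicle, averaged, 3094 for fluoxetine in HT, averaged, 671 for fluoxetine in WT, averaged, 1 for genotype by fluoxetine, averaged, 12 for sex by fluoxetine in HT, 2 for sex by lithium in WT. Then came 552 for drugs compared in WT males, 4269 for fluoxetine averaged over all.

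After quantile normalization they were 2 for genotype under vehicle, females, 1 for genotype under vehicle, males. With at least 50 normalized counts in 5 libraries they were 1 for fluoxetine in WT females, 26 for genotype under fluoxetine, males. With a pseudocount of 5 the number was 4 for genotype under vehicle, males. With the vehicle libraries split 2 and 3 between the contrasts the correlations were -0.05 for reversal by fluoxetine, females, -0.05 for reversal by lithium, females, 0.09 for overlap in HT females, -0.07 for overlap in WT females, 0.07 for reversal by fluoxetine, males, -0.13 for reversal by lithium, males, 0.06 for overlap in HT males, 0.18 for overlap in WT males. With genes of at least 50 normalized counts on average the correlation was -0.14 for reversal by fluoxetine, males. An estimated correlation left 6 for list tests. The fry test left 58 for list tests. The exact permutation left 22 for list tests.

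With each library left out in turn the numbers ran from 545 to 1345 for fluoxetine in HT females, 0 to 12 for sex by fluoxetine in HT, 390 to 1071 for drugs compared in HT females, 37 to 270 for fluoxetine in HT males, 1 to 49 for genotype under fluoxetine, males, 0 to 11 for genotype by fluoxetine, males, 1740 to 3146 for drugs compared in HT males, 31 to 456 for lithium in HT females. They ran from 0 to 20 for genotype under lithium, females, 0 to 2 for sex by lithium in HT, 0 to 118 for genotype under lithium, males, 0 to 1 for genotype by lithium, males, 0 to 3 for genotype under vehicle, females, 11 to 83 for genotype under vehicle, averaged, 0 to 77 for genotype under vehicle, males, 0 to 32 for fluoxetine in WT females. The next were 14 to 469 for fluoxetine in WT, averaged, 0 to 1 for sex by fluoxetine in WT, 669 to 1575 for drugs compared in WT females, 0 to 34 for fluoxetine in WT males, 37 to 426 for drugs compared in WT males, 11 to 322 for lithium in WT females, 0 to 146 for sex by lithium in WT, 50 to 447 for lithium in WT males. The correlations ran from -0.55 to -0.42 for reversal by fluoxetine, females, -0.53 to -0.38 for reversal by lithium, females, 0.44 to 0.54 for overlap in HT females, 0.29 to 0.47 for overlap in WT females, -0.45 to -0.21 for reversal by fluoxetine, males, -0.61 to -0.44 for reversal by lithium, males, 0.35 to 0.51 for overlap in HT males, 0.45 to 0.58 for overlap in WT males. List calls ran from 249 to 273, and all numbers for list tests cover genotypes and drugs against vehicle, within a sex and averaged over sexes.

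With olfactory bulb and striatal marker scores as covariates the direction turned for the myelinating oligodendrocyte markers in HT against WT under vehicle, averaged (adjusted p = 0.19 after the turn), and in WT fluoxetine, averaged (0.96). It turned for Slc35d3 under lithium in HT males (log2 fold change 0.06) and in HT averaged (0.18), and for Drd2 under lithium in HT averaged (0.01) and averaged over all (0.06); the striatal score takes in Drd2 itself, so the covariate removes it by construction. The overlap in WT females (-0.07) and the reversal by fluoxetine in males (0.07) turned with split vehicle libraries, as given above.

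With the replicate number as a block no number of genes called moved by more than 1.5 times: the replicate block gave 1844 for fluoxetine and 2644 for lithium in HT, averaged, and 42 and 829 in WT. Libraries with the same number did not vary together (mean correlation of their deviations from the group means 0.002, lowest -0.63), and 10 of 60 correlated best with their own number, so the numbers are not read as a pairing.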

Other observations

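The tests chosen after the result was seen were the 3 averaged contrasts, the batch and lithium-male tests, the comparison of striatal scores over all arms, the thinned reads and the exact permutation of list scores. Averaged over treatments and sexes, libraries labelled HT had 449 genes higher and 451 lower, and their Trip12 reads were not lower than in WT. Alox12b (0.61 ± 0.08, adjusted p = 6.3e-07, 30 of 30), a lipoxygenase, and the proliferation gene Mki67 (0.37 ± 0.10, adjusted p = 0.022, 24 of 30) rose. Myl4 (-0.31 ± 0.04, adjusted p = 6.3e-07, 30 of 30), a myosin light chain, Krt12 (-0.30 ± 0.04, adjusted p = 4.6e-07, 30 of 30), a keratin, and Pvalb (-0.30 ± 0.06, adjusted p = 0.00078, 26 of 30), the parvalbumin of fast-spiking interneurons, fell. Of 17 measured interferon-induced genes 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. Its mean log2 fold change was 0.15 (higher in 26 of 30 libraries, adjusted p = 0.35 with an estimated correlation). Of 19 measured proliferation genes 4 rose and 0 fell, or 10 and 0 adjusted over the list alone. The list's mean log2 fold change was 0.20 (higher in 25 of 30 libraries, adjusted p = 0.35 with an estimated correlation). Of 76 measured nuclear-encoded oxidative phosphorylation genes 0 rose and 18 fell, or 0 and 42 adjusted over the list alone. Over all measured members the mean log2 fold change was -0.08 (lower in 23 of 30 libraries, adjusted p = 0.35 with an estimated correlation). With length and GC slopes as covariates 5 of the oxidative phosphorylation genes fell.

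Averaged over genotypes and sexes, lithium had 2028 genes higher and 1993 lower, and fluoxetine 1195 and 1386. With lithium, Plekhg4 (0.94 ± 0.08, adjusted p = 2.7e-11, 20 of 20), Fkbp5 (0.77 ± 0.09, adjusted p = 3.9e-09, 20 of 20) and the neurotrophin gene Bdnf (0.47 ± 0.06, adjusted p = 9.7e-08, 20 of 20) rose, and Rims1 (-0.38 ± 0.05, adjusted p = 2.3e-07, 20 of 20) fell. Of 19 measured glucocorticoid-induced genes 16 rose and 0 fell, or 16 and 0 adjusted over the list alone. Members had a mean log2 fold change of 0.45 (higher in 20 of 20 libraries, adjusted p = 0.032 with an estimated correlation). Of 22 measured unfolded protein response genes 18 rose and 0 fell, or 18 and 0 adjusted over the list alone. The mean over members was a log2 fold change of 0.22 (higher in 19 of 20 libraries, adjusted p = 0.066 with an estimated correlation). Of 23 measured myelinating oligodendrocyte markers 0 rose and 16 fell, or 0 and 19 adjusted over the list alone. Their mean log2 fold change was -0.33 (lower in 18 of 20 libraries, adjusted p = 0.71 with an estimated correlation). Striatal markers averaged -0.66 with 11 of 17 called, and olfactory bulb markers -0.55 with 0 (-0.87 and 0 with fluoxetine). Lithium in WT gave means of -0.21 (striatal) and -0.27 (oligodendrocyte) with 0 called. With fluoxetine, Stard4 (-0.38 ± 0.04, adjusted p = 2.5e-09, 20 of 20) and Insig1 (-0.34 ± 0.03, adjusted p = 2.5e-09, 20 of 20) fell, and Zbtb16 (0.58 ± 0.07, adjusted p = 2.6e-08, 19 of 20) rose. Of 26 measured cholesterol synthesis genes 0 rose and 18 fell, or 1 and 22 adjusted over the list alone. The members' mean log2 fold change was -0.20 (lower in 20 of 20 libraries, adjusted p = 0.097 with an estimated correlation). A depth covariate gave 2466 genes for lithium and 491 for fluoxetine.

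Many genes were called for the drugs while depth followed treatment, so depth was weighed. With all libraries thinned to 25.1 M reads, fluoxetine in libraries labelled HT, averaged over sexes, had 1667 genes against 1824, 1585 of them shared. Thinning evens read numbers but cannot remove a bias that came with depth. Lithium had 2348 genes in males labelled HT, against at most 1007 in other splits. Exact permutation p = 0.29 for depth in these males does not show equal depth. A batch that follows treatment cannot be told apart from fluoxetine, since 0 fluoxetine libraries had totals in the vehicle range. A depth covariate left 778 genes. For both drugs, depth, batch and litter stay open beside the drug itself.

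Striatal markers were high in vehicle males labelled HT, and a difference in tissue taken at dissection may account for it. The slopes of 13704 genes outside the list on the striatal score, in the other groups (50 libraries), correlated at 0.46 across genes with the difference in vehicle males, but 100 shuffles gave -0.49 to 0.48, so tissue content stays open. A genotype effect shared by all arms stays open too: the score was higher in 4 of 6 arms, and lithium females labelled HT had -0.504 against -0.302 in WT (exact permutation p = 0.0079, BH-adjusted p = 0.15). Marker scores as covariates gave 1642 genes against 2595 for lithium in libraries labelled HT. An effect of the allele in untreated males was not separable from dissection.

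Trip12 reads were not lower in libraries labelled HT, which may mean labels without information, an allele whose transcripts are still counted, or sequence carried along with it. Labels without information are argued against: 1 of 100 splits within treatment and sex, the real one, called as many as 900 genes, and the highest other called 472. An allele still counted stays open, since Trip12 changed by 0.11 on the log2 scale and values per gene do not show its parts. Of 158 genes within 10 Mb of Trip12, 8 were called (5.06%), against 5.05% of the others (891 of 17645; one-sided Fisher's exact test p = 0.55), which leaves passenger sequence open.

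In 100 random splits of the libraries of each comparison (HT for libraries labelled HT), the real one included, genes called are given with the highest other split in parentheses. With 1 of 100 splits as large there were 1222 (16) for fluoxetine in HT females, 219 (130) for lithium in HT females, 2348 (1007) for lithium in HT males, 14 (9) for fluoxetine in WT males, 311 (6) for lithium in WT males, 14 (2) for genotype under fluoxetine, males, 1824 (240) for fluoxetine in HT, averaged. So were 2595 (1706) for lithium in HT, averaged, 814 (92) for lithium in WT, averaged, 10 (9) for males against females in WT vehicle, 983 (186) for drugs compared in HT females, 2836 (2088) for drugs compared in HT males, 1274 (675) for drugs compared in WT females, 900 (472) for genotype averaged over all. So were 2581 (38) for fluoxetine averaged over all, 4021 (7) for lithium averaged over all. With 2 of 100 splits as large there were 40 (166) for genotype under lithium, males, 27 (469) for genotype under vehicle, averaged. With 3 of 100 splits as large there were 106 (490) for fluoxetine in HT males, 145 (1160) for lithium in WT females, 37 (817) for fluoxetine in WT, averaged, 195 (893) for drugs compared in WT males. With 4 of 100 splits as large there were 2 (81) for genotype under vehicle, males. With 9 of 100 splits as large there were 1 (4) for genotype under vehicle, females. Where limma called 0, 100 of 100 splits gave as many by necessity, which decides nothing, and the highest others were 10 for fluoxetine in WT females, 2 for genotype under fluoxetine, females, 843 for genotype under lithium, females, 1 for genotype by fluoxetine, females, 2 for genotype by fluoxetine, males, 114 for genotype by lithium, females, 2 for genotype by lithium, males, 1 for genotype by fluoxetine, averaged, 87 for genotype by lithium, averaged, 611 for sex by genotype under vehicle, 1121 for sex by fluoxetine in HT, 1375 for sex by lithium in HT, 270 for sex by fluoxetine in WT, 110 for sex by lithium in WT. At a cut of 5 in 100 set beforehand, all comparisons with calls passed except genotype under vehicle in females, unadjusted for their number. Chance is argued against only where 1 of 100 was as large, if libraries are independent, and stays open elsewhere. For genotype in vehicle males a fit on only the libraries compared called 0. Splits with several times the real number, as for genotype under vehicle in males and averaged, fluoxetine in males labelled HT and in WT averaged, lithium in WT females, genotype under lithium, the drugs compared in WT males and several interactions, point to a structure of the samples other than their groups.

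Of 100 splits, the number in which camera called as many of the 39 lists as in the real one was as follows. It was 57 for genotype under vehicle, females (real 11, highest other 25), 2 for genotype under vehicle, males (real 18, highest other 18), 20 for fluoxetine in HT females (real 18, highest other 24), 1 for fluoxetine in HT males (real 19, highest other 18), 85 for lithium in HT females (real 7, highest other 23), 3 for lithium in HT males (real 22, highest other 22). Then 48 for fluoxetine in WT females (real 13, highest other 20), 86 for fluoxetine in WT males (real 10, highest other 23), 44 for lithium in WT females (real 13, highest other 22), 50 for lithium in WT males (real 10, highest other 19), 60 for genotype under fluoxetine, females (real 10, highest other 25), 66 for genotype under fluoxetine, males (real 15, highest other 22). There were 54 for genotype under lithium, females (real 12, highest other 24), 22 for genotype under lithium, males (real 14, highest other 22), 32 for genotype under vehicle, averaged (real 13, highest other 24), 17 for fluoxetine in HT, averaged (real 18, highest other 23), 17 for lithium in HT, averaged (real 16, highest other 23), 15 for fluoxetine in WT, averaged (real 17, highest other 21). Also 64 for lithium in WT, averaged (real 9, highest other 24), 56 for males against females in WT vehicle (real 11, highest other 24), 21 for genotype averaged over all (real 17, highest other 23), 9 for fluoxetine averaged over all (real 18, highest other 21), 22 for lithium averaged over all (real 16, highest other 22). Only genotype under vehicle in males and either drug in males labelled HT passed that cut. They share the HT vehicle males, so chance is not excluded, and camera calls at the preset correlation carry little weight alone.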
